A study of Arabidopsis thaliana with 9 samples.

How the data were processed

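RNA was taken from 7-day-old Arabidopsis thaliana seedlings, about 10 per sample, kept at 23 °C on 2.5 mM ammonium succinate as the nitrogen source, and treated for 15 min with 10 mM KCl or KNO3, per the labels' protocols. The protocols also describe 10 µM of an inhibitor given 2 min before the treatment, and the labels do not say which samples received it. Libraries were made with a kit that does not mark strand from 0.5 µg of RNA, and 9 barcoded libraries were sequenced over 2 lanes for 50 cycles, per the labels' protocols. Groups were taken from the sample titles: 3 libraries of wild type with KCl, 3 of wild type with KNO3 and 3 of icpk with KNO3. The titles also number the replicates from 1 to 3 in each group, and the replicate 3 libraries carry later accessions than replicates 1 and 2. Between wild type and icpk with KNO3, the deviations of same-numbered libraries from their group means correlated from 0.12 to 0.31 and those of others from -0.2 to 0.08. The numbers may therefore pair the libraries of this comparison. Deviations within a group sum to 0, so positive same-number values bring lower ones elsewhere, and the evidence is weak. Results come from the fit without a block, and blocked values stand beside those of this comparison where a call changed. What a number shares is not given in the labels.

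The authors deposited 1 table of raw counts per gene for each library, which are whole numbers with no normalization. TopHat, HTSeq, DESeq2 and the genome build TAIR10 are named per the submitters' processing notes, and their versions, the annotation release and the strand setting are not given in the sources used here. Without strand, reads from a gene and an overlapping antisense gene cannot be told apart, and counts of near-identical genes are uncertain. The count tables hold 32678 gene rows and 5 summary rows that name no gene. The summary rows took 26.7% to 84.3% of all records in a library and stayed out of library sizes and tests. Records aligned at more than 1 place made up 23.8% to 80.5% of all records. Gene counts per library ranged from 5987352 to 19564785.

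The authors also deposited 2 tables of their own comparisons. Per the file headers these hold a base mean signal of normalized counts, a log2 fold change with its standard error, a test score, and a p-value with its adjusted value, as DESeq2 names them. These deposited tables were used to count the authors' calls at an adjusted p below 0.05 and to set them beside the calls made here. Their fold changes and base means were also compared with those made here. The log2 fold changes of these tables and of the fits made here correlated across genes at 0.958 for the nitrate comparison and 0.965 for the icpk comparison. The deposited base mean equalled the mean of normalized counts made here, within a relative tolerance of 0.001, for 21.7% of rows. The best weighting of the 9 libraries was still off by a median of 1.97% over 16806 genes with a base mean above 50, so the authors' tables did not come from a weighting of these 9 count tables.

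Symbols came from the RefSeq annotation of assembly TAIR10.1, which matched 31912 of the 32678 identifiers. No coordinates are given, because that assembly is not the build named for the files. Counts were normalized with TMM factors and filtered with filterByExpr (minimum count 10), which left 20288 genes. Levels (CPM) are counts scaled to a fixed library total on TMM-scaled library sizes. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with all 9 libraries in 1 model with a mean per group, and calls had a Benjamini-Hochberg adjusted p below 0.05. The standard error of a log2 fold change is the fold change divided by the square root of F, which is approximate. The biological coefficient of variation was 15.1%. There were 3 comparisons: KNO3 against KCl in wild type, icpk against wild type with KNO3, and, as a secondary one, icpk with KNO3 against wild type with KCl.

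Before the data were examined, 23 gene lists were fixed from general knowledge, with 331 genes besides the 3 targeted kinases, of which 311 were tested. Lists were tested with fry (limma 3.58.1), whose p asks whether the genes of a list move on balance in 1 direction, adjusted over the 23 lists. The test camera with an estimated correlation between genes was the alternative, and 3, 1 and 4 lists passed with it in the 3 comparisons, against 13, 13 and 11 with fry. Counts adjusted over the list alone use the same p-values adjusted within the list. The genes named were chosen by a rule fixed at the same time. It takes CPK10, CPK30 and CPK32 always. In each main comparison it takes the 6 largest rises and 6 largest falls among called genes with an average of at least 1 log2 CPM whose libraries do not overlap between groups. From each list it takes up to 4 called members by smallest p, or up to 6 from 3 lists on nitrate uptake, nitrate regulators and NIN-like proteins. Where the reference has another symbol, or none, it or the identifier is printed beside the common name.

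A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group, and a gene with 1 to 3 pooled counts as a ratio with an exact 95% binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The replicates were compared before averaging, and every pair within a group differed by more than sampling noise (chi-square per gene from 11.0 to 90.4). In simulated data for the nitrate comparison, with 200 of 20288 genes changed, the edgeR test recovered 68% of the 2-fold and 95% of the 4-fold changes, with 6.32% false among its calls and 2 calls where nothing was changed. DESeq2 gave 18.0% false among its calls and limma voom 8.05%. The simulated list that was changed gave a fry p of 1.02e-06 and an unchanged one 0.355.

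The alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test (DESeq2 1.42.0), limma voom, the 6 libraries of a comparison alone, the replicate number as a block, a minimum 2-fold change, each library left out in turn, and replicate 3 of every group left out. A fit without organelle and rRNA genes was added after wild type KCl replicate 3 was seen to hold many of them.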

Results

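Gene expression was measured by RNA sequencing in 7-day-old Arabidopsis thaliana seedlings, in 3 groups of 3 libraries each. Wild type seedlings grown on ammonium succinate as the sole nitrogen source received 10 mM KCl or 10 mM KNO3 for 15 min, and icpk seedlings received 10 mM KNO3 for 15 min. The icpk line is mutated in the calcium-dependent protein kinases CPK10, CPK30 and CPK32 and carries an engineered CPK10 that a small molecule can inhibit. KCl supplies the same potassium with chloride in place of nitrate. The wild type libraries thus give the response to nitrate if the inhibitor was given alike in both groups, which the labels do not state. The icpk libraries address how far that response depends on the 3 kinases. No icpk libraries with KCl were analysed here, so a difference between icpk and wild type can be a change in the nitrate response, a difference that was there before nitrate, or an effect of the inhibitor, since the labels do not say which samples received it. The libraries held 19564785, 15480526 and 5987352 counts in genes with KCl, 14265988, 17126496 and 14491493 in wild type with KNO3, and 11822413, 18366578 and 15597777 in icpk. Wild type KCl replicate 3 stood apart, with 80.5% of its records aligned at more than 1 place and 8.82% of its gene counts in organelle and rRNA genes, against 23.8% and 0.703% in wild type KNO3 replicate 2. About 10 seedlings were pooled per sample, and the labels do not state that the libraries of a group came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

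The targeted kinases came out as follows. CPK30 stood at 27.5 ± 1.11 CPM (counts scaled to library size, SD, n = 3) in wild type with KNO3 and at 3.39 ± 0.484 CPM in icpk, which is 12.3% of the wild type level (log2 difference -3.02 ± 0.13 SE, adjusted p = 5.19e-06). CPK32 stood at 206 ± 6.86 and 21.3 ± 3.34 CPM, or 10.4% (log2 difference -3.27 ± 0.23, adjusted p = 6.42e-05). CPK10, listed as CDPK1 in the reference, was higher in icpk, at 160 ± 9.52 CPM against 90.12 ± 9.79 CPM (177% of wild type, adjusted p = 0.00147), and counts per gene do not separate the introduced CPK10 from the native gene. In wild type, none of the 3 passed the test between KNO3 and KCl, with log2 changes of 0.35 ± 0.12 for CPK10, 0.12 ± 0.11 for CPK30 and 0.03 ± 0.20 for CPK32.

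**Figure D1:**
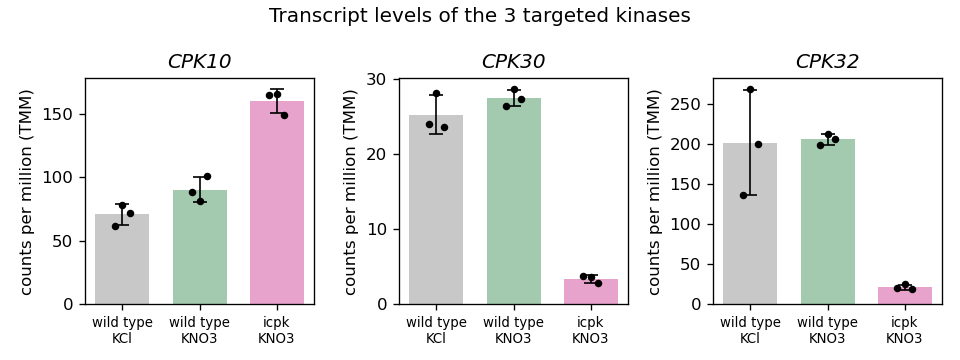
CPM of CPK10, CPK30 and CPK32 in the 9 libraries. Bars give the mean of 3 libraries, error bars the SD and points the single libraries; CPK30 and CPK32 in icpk lie at 12.3% and 10.4% of wild type with KNO3, and CPK10 at 177%.

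Nitrate raised the genes that take nitrate up and reduce it within 15 min in wild type. NIR1, the nitrite reductase, rose from 210 ± 44.0 to 1977 ± 95.1 CPM (SD, n = 3; log2 fold change 3.24 ± 0.18 SE, adjusted p = 1.46e-06). NIA2, a nitrate reductase, rose from 469 ± 77.9 to 1640 ± 178 CPM (1.81 ± 0.16), and the high-affinity transporter NRT2.1 (NRT2:1 in the reference) from 18.1 ± 4.99 to 203 ± 23.5 CPM (3.51 ± 0.19). In all, 722 genes were higher and 485 lower with KNO3 than with KCl among 20288 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 398 and 123 of them changed at least 2-fold. Of the 18 tested genes of nitrate uptake and reduction, 9 rose, 0 fell and 9 did not pass (11 rose when adjusted over the list alone). The median log2 fold change was 0.67 and the list rose (fry, adjusted p = 9.81e-07), as it did with an estimated correlation (adjusted p = 0.000206). Root markers had a median of 0.26 and shoot photosynthesis markers of -0.54, and neither list passed (given below). UPM1, which makes siroheme for nitrite reductase, rose by 3.2 ± 0.12 on the log2 scale, and NRT3.1 (WR3), the partner protein of NRT2.1, by 2.94 ± 0.12. NRT2.2 went from 2 to 494 pooled counts over the group, a ratio of 211 with a 95% counting interval from 58.0 to 1745. Among 8 other nitrate transporters 3 rose: NRT1.7 (1.13 ± 0.10), NRT2.4 (2.26 ± 0.35) and NRT2.5 (3.06 ± 0.63). That list's median was 0.04 and it was called higher (adjusted p = 0.0145), but not with an estimated correlation (adjusted p = 0.169). It lost its call without wild type KCl replicate 1 (adjusted p = 0.052), and NRT2.5 lost its call without wild type KCl replicates 2 and 3 (0.0904 and 0.051) and wild type KNO3 replicates 1 and 3 (0.0567 and 0.0508). NRT2.5 was not called with limma voom (0.117) or without replicate 3 of every group (0.137) either, and its log2 change was 3.70 without wild type KCl replicate 1 and 2.45 without wild type KNO3 replicate 3.

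Regulators of the nitrate response rose most uniformly. Of 19 tested nitrate-responsive regulators, 18 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 1.64 (fry, adjusted p = 4.37e-06; adjusted p = 0.000206 with an estimated correlation). The scaffold protein gene BT2 rose from 1.08 ± 0.986 to 59.7 ± 9.12 CPM (5.56 ± 0.34, adjusted p = 3.44e-06, and 6.3 without wild type KCl replicate 2) and BT1 from 4.78 ± 1.65 to 124 ± 7.83 CPM (4.73 ± 0.22). The LBD repressors of nitrogen genes rose together, LBD37 by 2.74 ± 0.17, LBD38 by 2.25 ± 0.13 and LBD39 by 3.24 ± 0.14 on the log2 scale. HHO1 (AT3G25790) rose by 5.91 ± 0.64 and HHO2 (AT1G68670) by 1.82 ± 0.11. In the family of NIN-like proteins and their partners, 3 of 11 rose and 2 fell (4 and 2 adjusted over the list alone). NLP3 (AT4G38340) rose from 4.65 ± 1.15 to 68.7 ± 14.0 CPM (3.92 ± 0.24), while NLP4 (AT1G20640) and NLP6 (AT1G64530) fell by 0.41 ± 0.09 and 0.35 ± 0.08. Both calls were lost with fewer libraries, where the log2 changes ran from -0.32 to -0.42 for NLP4 and from -0.30 to -0.39 for NLP6. Without wild type KCl replicates 2 and 3 and wild type KNO3 replicates 1 and 3, the adjusted p was 0.0866, 0.093, 0.0857 and 0.0923 for NLP4 and 0.109, 0.106, 0.135 and 0.079 for NLP6, and NLP6 had 0.0598 without wild type KCl replicate 1. With the 6 libraries of the comparison alone it was 0.0553 and 0.0549, and without replicate 3 of every group 0.162 and 0.15, with log2 changes of -0.30 and -0.31. This list was called higher (median 0.15, adjusted p = 0.00196), but not with an estimated correlation (adjusted p = 0.129).

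Transcripts of part of the genes that supply plastids with reducing power rose with nitrate. Of 19 genes of the oxidative pentose phosphate pathway and root ferredoxin reduction, 7 rose, 0 fell and 12 did not pass (10 and 3 adjusted over the list alone; median 0.35, fry adjusted p = 9.81e-07, and 0.000206 with an estimated correlation). G6PD3 rose from 19.1 ± 5.75 to 363 ± 12.0 CPM (4.29 ± 0.19, adjusted p = 3.29e-07), G6PD2 by 2.98 ± 0.10, the phosphogluconate dehydrogenase PGD3 (AT5G41670) by 3.43 ± 0.13 and the root ferredoxin reductase RFNR1 by 3.05 ± 0.10. Of 16 genes of ammonium assimilation and transport, 3 rose and 2 fell (8 and 2 adjusted over the list alone). The glutamate synthase GLT1 rose by 0.79 ± 0.14 and the asparagine synthetase ASN2 by 1.21 ± 0.10, and the glutamate dehydrogenases GDH1 and GDH2 fell by 0.80 ± 0.11 and 1.07 ± 0.17. The list was called higher (median 0.37, adjusted p = 0.00682), but not with an estimated correlation (adjusted p = 0.129).

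**Figure D2:**
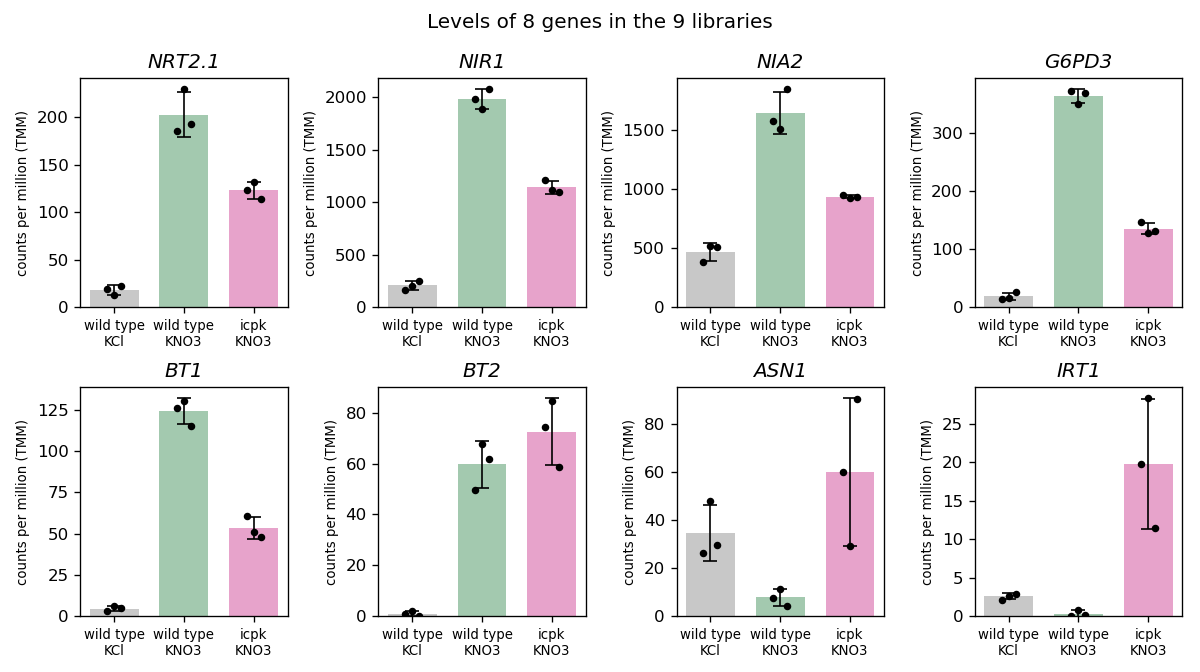
CPM of 8 genes in the 9 libraries, with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. NIR1 lies near 1977 CPM in wild type with KNO3 and 1140 CPM in icpk, BT2 near 59.7 and 72.5 CPM, and IRT1 near 0.352 and 19.8 CPM.

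Hormone genes changed in part. The cytokinin synthesis genes IPT3 (3.17 ± 0.24) and CYP735A2 (1.84 ± 0.23) were the 2 of 13 cytokinin genes that rose (6 and 2 lower adjusted over the list alone; list median 0.48, adjusted p = 0.0140, and 0.164 with an estimated correlation). Of 9 type-A response regulators 3 rose, led by ARR3 (3.02 ± 0.24), with 3 adjusted over the list alone, a median of 0.05 and adjusted p = 0.0149 (0.164 with an estimated correlation). Of 16 auxin genes 4 rose and 1 fell (6 and 2 adjusted over the list alone). The auxin synthesis gene TAR2 rose by 1.18 ± 0.10 and GH3.3 fell by 1.03 ± 0.22 (list median 0.20, adjusted p = 0.0197, and 0.235 with an estimated correlation). Without wild type KCl replicate 1 the cytokinin (adjusted p = 0.052), type-A (0.0676) and auxin lists (0.075) lost their calls, as did the auxin list without wild type KCl replicate 2 (0.0708) and wild type KNO3 replicate 3 (0.0558). GH3.3 lost its call without wild type KCl replicates 2 and 3 (0.0919 and 0.0645) and wild type KNO3 replicates 1 and 3 (0.0718 and 0.0572), and without replicate 3 of every group (0.0909). Of 5 CC-type glutaredoxins, small redox proteins with near-identical copies whose counts are uncertain, 3 rose (4 adjusted over the list alone), with a list median of 1.56 (adjusted p = 0.000471, and 0.0517 with an estimated correlation). GRXS4 (AT4G15680) had 0 counts with KCl and was at least 9.10-fold higher with KNO3 against a floor of 3 counts over the group (4.53-fold and 5.78-fold without wild type KCl replicates 1 and 2); its call was lost without wild type KCl replicates 1 and 2 (adjusted p = 0.0768 and 0.0614) and wild type KNO3 replicate 1 (0.0656). Of 11 phosphate starvation genes 2 rose, PPCK1 (2.18 ± 0.13) and the galactolipid synthase MGD3 (MGDC, 1.99 ± 0.33), and 4 rose and 1 fell adjusted over the list alone (median 0.19, adjusted p = 0.00106, and 0.0517 with an estimated correlation).

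Genes that fell with nitrate included markers of low energy, beside shoot photosynthesis markers with a median of -0.54. The asparagine synthetase ASN1 fell from 34.6 ± 11.6 to 7.92 ± 3.56 CPM (-2.12 ± 0.44, adjusted p = 0.0174) and SEN1 from 32.0 ± 4.93 to 7.51 ± 3.66 CPM (-2.10 ± 0.32). ASN1 lost its call without wild type KCl replicate 2 (adjusted p = 0.0769) and wild type KNO3 replicates 1 and 3 (0.077 and 0.062), and without replicate 3 of every group (0.0636). Of the 16 genes of that list 4 fell and 2 rose (7 and 2 adjusted over the list alone), and the list was not called (median -0.29, adjusted p = 0.141). The iron transporter IRT1 fell by 2.73 ± 0.64 on the log2 scale and OPT3 by 0.53 ± 0.13. These were the 2 of 7 iron deficiency genes called, also adjusted over the list alone (median -0.29, adjusted p = 0.00411, and 0.193 with an estimated correlation). Both calls were lost with fewer libraries, where the log2 changes ran from -2.27 to -2.87 for IRT1 and from -0.49 to -0.56 for OPT3. Without wild type KCl replicates 1, 2 and 3 and wild type KNO3 replicates 1 and 3, the adjusted p was 0.0741, 0.104, 0.0703, 0.107 and 0.11 for IRT1 and 0.0903, 0.14, 0.0963, 0.158 and 0.12 for OPT3, and OPT3 had 0.0636 without icpk replicate 1. Without replicate 3 of every group it was 0.115 and 0.0847, and IRT1 was not called with limma voom (0.0817). Without wild type KNO3 replicate 2 IRT1 fell by 4.57 (adjusted p = 0.00398). Of 16 clock genes 2 fell and 1 rose (3 and 1 adjusted over the list alone). PIF4 fell by 0.97 ± 0.22 and PRR7 by 0.85 ± 0.18 (list median -0.12, adjusted p = 0.00682, and 0.231 with an estimated correlation). PIF4 lost its call without wild type KCl replicates 1 and 2 (0.106 and 0.0676) and wild type KNO3 replicate 3 (0.0854), and PRR7 without wild type KCl replicates 1 and 2 (0.0735 and 0.0732). The other large falls were CYP71A20 (-3.04 ± 0.38, and -3.67 without wild type KNO3 replicate 2), AT4G36850 (-2.37 ± 0.42, and -3.02 without that library) and AT1G32970 (-2.09 ± 0.21). Large rises outside the lists were AT3G44800 (5.41 ± 0.32), AT2G36540 (4.98 ± 0.51, and 6.14 without wild type KCl replicate 1) and AT5G15060, which had 0 counts with KCl and was at least 84.2-fold higher with KNO3 (41.9-fold and 53.4-fold without wild type KCl replicates 1 and 2).

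The other lists did not pass the test with KNO3. They were the CPK family (17 tested, 1 higher, median 0.04, adjusted p = 0.265), touch and rapid stress genes (18 tested, 3 higher, among them CBF2 by 2.47 ± 0.23, median 0.30, 0.0764) and jasmonate genes (19 tested, 2 lower, 5 lower adjusted over the list alone, median -0.71, 0.105). Heat shock genes (9 tested, 0 called, 1 lower adjusted over the list alone, median -0.32, 0.0894), abscisic acid genes (13 tested, 1 higher, 1 and 1 lower adjusted over the list alone, 0.15, 0.45) and sulfate genes (8 tested, 1 higher and 1 lower, 1 and 3 adjusted over the list alone, -0.04, 0.45) did not pass either. Nor did root markers (20 tested, 0 called, 3 higher adjusted over the list alone, median 0.26, 0.265), ribosome assembly genes (8 tested, 0.09, 0.119) or shoot photosynthesis markers (15 tested, 1 lower, 2 adjusted over the list alone, -0.54, 0.0596). Without wild type KNO3 replicate 2 the touch list (0.0416) and the photosynthesis list (0.0334) were called, without icpk replicate 2 the photosynthesis list (0.0357) and without icpk replicate 3 the heat shock list (0.0456). The fall of CAB3, the photosynthesis marker called (-1.03 ± 0.25), lost its call without wild type KCl replicates 1, 2 and 3 (0.0903, 0.127 and 0.0802), wild type KNO3 replicates 1 and 3 (0.092 and 0.108) and icpk replicate 1 (0.0556), and without replicate 3 of every group (0.1). The count of lower genes moved with the libraries used: it went from 485 to 224, 141 and 315 without wild type KCl replicates 1, 2 and 3, and to 125, 1231 and 183 without wild type KNO3 replicates 1, 2 and 3. The count of higher genes went from 722 to 476 without wild type KCl replicate 2 and to 473 without wild type KNO3 replicate 1. The authors' deposited table called 975 genes higher and 879 lower, of which 703 and 454 were also called here and 0 the other way.

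In icpk, many nitrate-raised genes stood lower than in wild type under KNO3. NIR1 stood at 1140 ± 59.0 CPM against 1977 ± 95.1 CPM (log2 difference -0.79 ± 0.16, adjusted p = 0.00764), NIA2 at 935 ± 15.3 against 1640 ± 178 CPM (-0.81 ± 0.15) and G6PD3 at 136 ± 10.2 against 363 ± 12.0 CPM (-1.42 ± 0.16, adjusted p = 0.000738). In all, 2286 genes were higher and 2313 lower in icpk, 370 and 732 of them at least 2-fold. Of 18 genes of nitrate uptake and reduction, 10 were lower and 1 higher, also adjusted over the list alone (median -0.48, adjusted p = 0.000236, and 0.0599 with an estimated correlation). NRT2.2 was at -3.82 ± 0.45, NRT3.1 (WR3) at -0.86 ± 0.11 and UPM1 at -0.72 ± 0.11. NRT1.8 was lower too, at -1.73 ± 0.31, though its change with KNO3 in wild type did not pass (-0.01 ± 0.29, adjusted p = 0.992). Root markers moved the same way without passing (4 of 20 lower and 0 higher, median -0.28, adjusted p = 0.116, and 0.0493 without icpk replicate 2), and shoot photosynthesis markers the other way (median 0.53). Of 8 other nitrate transporters 4 were lower and 1 higher (5 and 1 adjusted over the list alone), with NRT2.4 at -2.17 ± 0.34 and NRT2.5 at -3.18 ± 0.62 (list median -0.47, adjusted p = 0.00800, and 0.224 with an estimated correlation). NRT2.5 was at -2.57 without wild type KNO3 replicate 3, and without replicate 3 of every group NIA2 (0.0586), NRT1.8 (0.0512) and NRT2.5 (0.0686) were not called.

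Some of the other lists raised by nitrate were lower too, while those of ammonium assimilation, cytokinin, type-A response regulators and phosphate starvation were not called (adjusted p = 0.0885, 0.116, 0.956 and 0.107). With the replicate block the ammonium (0.0277) and cytokinin lists (0.0107) were called lower as well. Root markers moved with these lists (median -0.28). Of 19 nitrate-responsive regulators 11 were lower and 0 higher, also adjusted over the list alone (median -0.50, adjusted p = 0.00141, and 0.0884 with an estimated correlation). BT1 was lower by -1.22 ± 0.17, CDF1 by -0.96 ± 0.18, CIPK8 by -0.66 ± 0.13, LBD39 by -0.62 ± 0.12 and TGA4 by -0.60 ± 0.11. BT2 stood at 72.5 ± 13.1 CPM against 59.7 ± 9.12 CPM (0.28 ± 0.23, adjusted p = 0.413) and HHO1 at 5.16 ± 3.07 against 6.38 ± 1.46 CPM (-0.28 ± 0.35, adjusted p = 0.602), and neither passed. The NIN-like list was lower (4 of 11, with 6 lower and 1 higher adjusted over the list alone; median -0.27, adjusted p = 0.00142, and 0.157 with an estimated correlation). NLP3 was at -1.73 ± 0.21, NLP1 (AT2G17150) at -0.89 ± 0.10 and NLP5 (AT1G76350) at -0.59 ± 0.11. The change of NLP5 with KNO3 in wild type did not pass (0.13 ± 0.11, adjusted p = 0.529). Of 19 pentose phosphate and ferredoxin genes 9 were lower and 3 higher (9 and 4 adjusted over the list alone; median -0.30, adjusted p = 0.000637, and 0.0884 with an estimated correlation), with RFNR1 at -1.02 ± 0.10 and G6PD2 at -0.99 ± 0.09. Auxin genes were mixed, with 6 lower and 4 higher of 16 (7 and 4 adjusted over the list alone; median -0.24, adjusted p = 0.0363, and 0.438 with an estimated correlation). IAA19 was at -1.57 ± 0.17 and GH3.3 at 1.23 ± 0.22. The auxin list lost its call without wild type KCl replicates 1 and 2 (adjusted p = 0.0548 and 0.053), wild type KNO3 replicates 2 and 3 (0.072 and 0.102) and icpk replicates 1 and 2 (0.0813 and 0.0779).

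Rapid stress genes were lower in icpk and low-energy genes higher, beside root markers with a median of -0.28 and shoot photosynthesis markers with 0.53. Of 18 touch and rapid stress genes 13 were lower and 0 higher (17 lower adjusted over the list alone), with a median of -1.20 (adjusted p = 0.00157, and 0.0884 with an estimated correlation). ERF105 (AT5G51190) stood at 21.0 ± 3.68 CPM against 85.8 ± 2.25 CPM (-2.02 ± 0.14, adjusted p = 6.42e-05), ERF5 at -1.44 ± 0.14, ZAT10 (STZ) at -1.25 ± 0.17 and ERF104 at -1.14 ± 0.14. Their changes with KNO3 in wild type did not pass the test, at 0.31 ± 0.13, -0.20 ± 0.14, 0.21 ± 0.17 and 0.35 ± 0.14. In the CPK family, which here leaves out the 3 targeted genes, 8 of 17 were lower and 0 higher (10 lower adjusted over the list alone; median -0.38, adjusted p = 0.00618, and 0.274 with an estimated correlation), with CPK29 at -1.28 ± 0.24 and CPK2 at -1.03 ± 0.18. Of 16 low-energy genes 12 were higher and 0 lower (13 adjusted over the list alone; median 0.97, adjusted p = 0.00204, and 0.0884 with an estimated correlation). ASN1 stood at 60.0 ± 30.6 against 7.92 ± 3.56 CPM (2.91 ± 0.44), SEN1 at 2.36 ± 0.32, DIN10 at 1.95 ± 0.24 and SEN5 (AT3G15450) at 1.85 ± 0.22. GDH1 (0.81 ± 0.11) and GDH2 (0.88 ± 0.17), which fell with nitrate in wild type, were higher in icpk. Without replicate 3 of every group ASN1 was at 2.17 and GDH2 was not called (0.0538).

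Iron deficiency genes were higher in icpk. IRT1 stood at 19.8 ± 8.44 CPM against 0.352 ± 0.441 CPM in wild type with KNO3 and 2.6 ± 0.378 CPM with KCl (5.71 ± 0.54, adjusted p = 0.000304). Its counts in single wild type KNO3 libraries ran from 1 to 15, and without wild type KNO3 replicate 2 the log2 difference was 7.55. OPT3 (1.25 ± 0.13) and BTS (0.47 ± 0.09) were also higher, and BHLH101 had 46 pooled counts against 3, a ratio of 16.4 with a 95% counting interval from 5.28 to 82.6 (31.4 without wild type KNO3 replicate 2). Of 7 tested members 5 were higher, also adjusted over the list alone (median 1.19, adjusted p = 7.89e-05), and this was the 1 list that passed in icpk with an estimated correlation (adjusted p = 0.0432). Clock genes were higher (5 of 16, also adjusted over the list alone; median 0.31, adjusted p = 0.000577, and 0.0884 with an estimated correlation), with PIF4 at 1.33 ± 0.21 and PRR9 at 1.15 ± 0.30. Of 15 shoot photosynthesis markers 3 were higher (4 adjusted over the list alone; median 0.53, adjusted p = 0.0426, and 0.438 with an estimated correlation). The carbonic anhydrase CA1 stood at 2.39 ± 0.32, RBCS1B at 1.21 ± 0.25 and CAB3 at 0.92 ± 0.25; RBCS and CAB genes have near-identical copies, so their counts are uncertain. The photosynthesis list was not called with the replicate block (adjusted p = 0.0973). It lost its call without wild type KCl replicates 1, 2 and 3 (0.0664, 0.0576 and 0.0739), wild type KNO3 replicates 1 and 3 (0.0988 and 0.12) and icpk replicates 1 and 3 (0.112 and 0.0976). CAB3 lost its call without wild type KNO3 replicates 1 and 3 (0.0549 and 0.0705) and icpk replicates 1 and 3 (0.0619 and 0.081), and PRR9 without wild type KNO3 replicates 2 and 3 (0.0589 and 0.0633) and icpk replicates 2 and 3 (0.0593 and 0.0587). CAB3 was not called with the 6 libraries of the comparison alone (0.0547), nor were CAB3 (0.192), PRR9 (0.133) and RBCS1B (0.108) without replicate 3 of every group. CC-type glutaredoxins were called lower (adjusted p = 0.00618, and 0.438 with an estimated correlation) through CEPD2 (AT2G47880, -2.61 ± 0.36), 1 of 5 genes, also adjusted over the list alone, while the list's median was 0.06 and its mean -0.46.

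**Figure D3:**
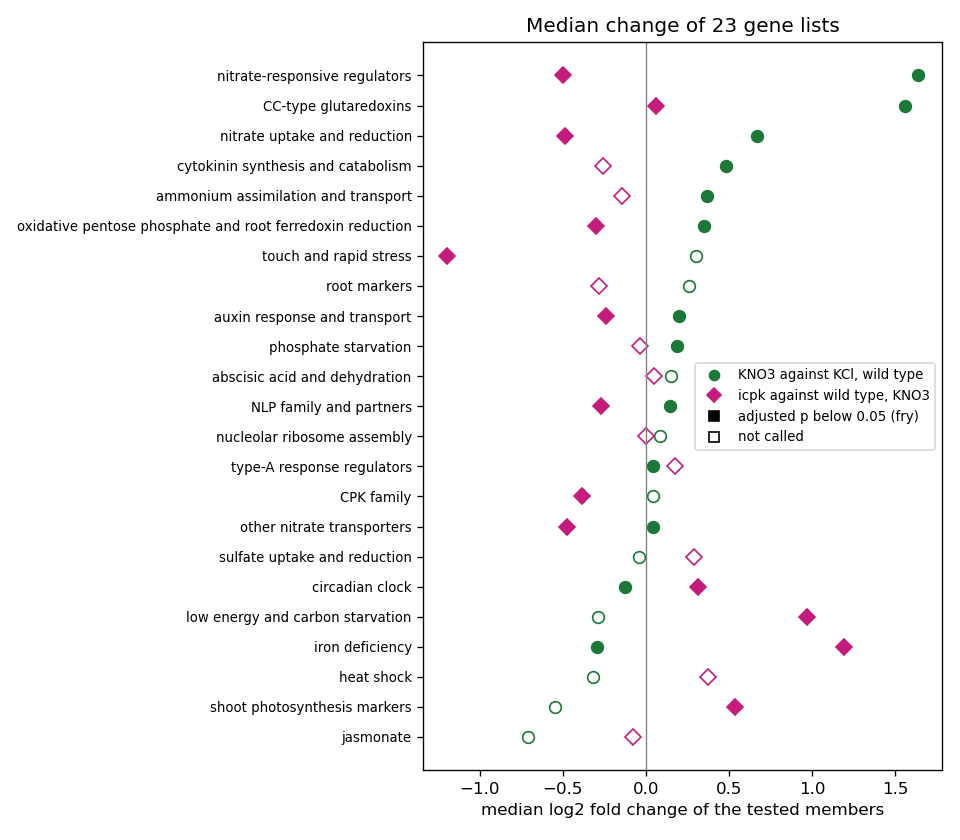
Median log2 fold change of the tested members of 23 gene lists, circles for KNO3 against KCl in wild type and diamonds for icpk against wild type with KNO3; filled symbols passed the fry test at adjusted p below 0.05. The nitrate-responsive regulators lie at 1.64 and -0.50, touch and rapid stress genes at 0.30 and -1.20, and iron deficiency genes at -0.29 and 1.19.

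The remaining lists were not called between icpk and wild type. They were ammonium assimilation (16 tested, 7 lower and 2 higher, median -0.15, adjusted p = 0.0885), cytokinin genes (13 tested, 3 lower and 1 higher, -0.26, 0.116) and type-A response regulators (9 tested, 1 lower and 1 higher, median 0.18, mean 0.01, tested as lower with 0.956). Jasmonate (19 tested, 1 lower and 1 higher, -0.08, 0.764), heat shock (9 tested, 0.37, 0.267), abscisic acid (13 tested, 2 higher, 0.05, 0.25) and sulfate genes (8 tested, 2 higher, 0.29, 0.156) did not pass. Root markers (20 tested, 4 lower, -0.28, 0.116), ribosome assembly genes (8 tested, 1 lower, 0.00, 0.750) and phosphate starvation genes (11 tested, 3 lower and 1 higher, -0.03, 0.107) did not pass either. With the replicate block ammonium assimilation (adjusted p = 0.0277) and cytokinin genes (0.0107) were called, and type-A response regulators were tested as higher (0.839). Without icpk replicate 3 the ammonium (0.0424), cytokinin (0.0202) and sulfate lists (0.0488) were called, and without icpk replicate 2 the root markers (0.0493). Outside the lists, the largest rises were AT3G59940 (2.93 ± 0.24), AT5G05250 (2.83 ± 0.42, and 3.59 without wild type KNO3 replicate 2), AT5G38910 (2.6 ± 0.55, not called without replicate 3 of every group, 0.0955) and AT4G31330 (2.53 ± 0.39). Among the largest falls, besides AT3G41979 and CRA1 given next, were AT1G34047 (from 1129 ± 232 to 33.3 ± 9.16 CPM), AT2G36255 (-4.72 ± 0.54, and -4.10 without wild type KNO3 replicate 2) and the metal transporter genes MTPA1 (-4.54 ± 0.36) and ZIP12 (-4.51 ± 0.58). AT3G41979, an rRNA gene (-4.94 ± 1.16), was a further fall with a wide spread, not called without icpk replicate 3 (adjusted p = 0.0522) or with limma voom (0.0594). The seed storage gene CRA1 had 368 pooled counts in wild type with KNO3 against 2 in icpk, a ratio of 172 with a 95% counting interval from 47.2 to 1423, and held from 11 to 314 counts in single wild type KNO3 libraries. Its ratio was 36.8 without wild type KNO3 replicate 3, and limma voom did not call it (adjusted p = 0.0596). The counts of higher and lower genes went from 2286 and 2313 to 1082 and 1379 without wild type KNO3 replicate 1 and to 1328 and 1516 without replicate 3. The count of higher genes went to 1437 and 1445 without icpk replicates 1 and 3. The authors' deposited table called 2495 genes higher and 2478 lower in icpk, of which 2139 and 2128 were also called here and 0 the other way.

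Most genes raised by nitrate were lower in icpk, while most genes called in icpk were not called with KNO3. Of the 4599 genes called in icpk, 817 were also called with KNO3 and 3782 were not. A missing call does not show that a gene was unchanged by nitrate. Of the 722 genes higher with KNO3, 456 were lower in icpk and 10 higher, and of the 485 genes lower with KNO3, 336 were higher in icpk and 15 lower. Independent lists of these sizes would share 82.3 and 54.6 genes in the opposite direction. Both comparisons use the wild type KNO3 libraries, and in 20 simulations of unchanged groups the opposite overlaps reached at most 1 gene each. With no group different hardly any gene is called, so these counts cannot show what the sharing adds among real calls. The log2 fold changes of the 2 comparisons correlated across genes, which are not independent replicates, at -0.54, against -0.48 in the simulations. Their covariance was -0.144 against a simulated -0.030, a difference of -0.114. With 3 wild type KNO3 libraries the shared libraries could not be divided into parts of at least 2, so part of the overlap may come from them. The 336 shared genes became 104, 100 and 252 without wild type KCl replicates 1, 2 and 3, and 74, 999 and 99 without wild type KNO3 replicates 1, 2 and 3. They became 207 without icpk replicate 1, and the 456 became 304 and 253 without wild type KCl replicate 1 and wild type KNO3 replicate 1.

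Against wild type with KCl, icpk with KNO3 still showed part of the nitrate-raised set. NRT2.1 was higher (2.79 ± 0.19, adjusted p = 1.14e-05), as were NIR1 (2.45 ± 0.17), G6PD3 (2.87 ± 0.18), BT1 (3.52 ± 0.21), BT2 (5.84 ± 0.34, and 6.58 without wild type KCl replicate 2) and IPT3 (2.97 ± 0.24). NRT2.4 (0.09 ± 0.36), NRT2.5 (-0.12 ± 0.76), NLP1 (0.14 ± 0.11), CIPK8 (0.04 ± 0.13), ASN1 (0.78 ± 0.40) and SEN1 (0.27 ± 0.30) did not pass the test. Of 20288 genes 639 were higher and 779 lower, and 309 of the 722 nitrate-raised genes were among the higher ones (22.7 for independent lists). Both comparisons use the wild type KCl libraries, and in the 20 simulations of unchanged groups this overlap reached at most 0 genes. Hardly any gene is called in such simulations, so that count cannot show what the sharing adds among real calls. With 3 wild type KCl libraries these could not be divided into parts of at least 2, so part of the overlap may come from them. Of the 456 nitrate-raised genes that were lower in icpk, 139 were still above the wild type KCl level and 7 below it. Of the 336 nitrate-lowered genes that were higher in icpk, 2 were still below it. Both sets were chosen by calls against wild type with KNO3 that move icpk toward or past the wild type KCl level. The numbers 139 and 2 therefore follow in part from that choice. Genotype and treatment differ together in this comparison. The counts of higher and lower genes went to 354 and 335 without wild type KCl replicate 2. They went to 356 and 375 without wild type KCl replicate 3, and the lower count to 412 without icpk replicate 3.

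Among the lists, those of nitrate uptake and reduction (9 of 18 higher, 1 lower; 10 and 1 adjusted over the list alone; median 0.48), nitrate-responsive regulators (13 of 19 higher, 15 adjusted over the list alone, 1.31) and pentose phosphate and ferredoxin genes (8 of 19 higher, 9 adjusted over the list alone, 0.38) were higher in icpk with KNO3 than in wild type with KCl. Their adjusted p was 9.20e-06, 1.97e-05 and 9.20e-06, and 0.000986 for each with an estimated correlation. Iron deficiency genes were higher (5 of 7, also adjusted over the list alone, 0.72, adjusted p = 0.000661, and 0.0240 with an estimated correlation). Low-energy genes (7 of 16 higher, 11 adjusted over the list alone, median 0.72, adjusted p = 0.00846) and CC-type glutaredoxins (3 of 5 higher, 3 and 1 lower adjusted over the list alone, 2.17, 0.00717) were higher, with 0.123 and 0.192 as adjusted p with an estimated correlation. Phosphate starvation genes (1 of 11 higher, 0.11, 0.00523), type-A response regulators (2 of 9 higher, 5 adjusted over the list alone, 0.54, 0.0174) and clock genes (1 of 16 higher, 0.11, 0.0174) were called higher, with an adjusted p of 0.123, 0.175 and 0.357 with an estimated correlation. Touch and rapid stress genes (9 of 18 lower and 2 higher, 13 and 3 adjusted over the list alone, -0.93, 0.0174) and the CPK family (2 of 17 lower, 7 adjusted over the list alone, -0.20, 0.0299) were called lower, with an adjusted p of 0.187 and 0.357 with an estimated correlation. The CPK family lost its call without wild type KCl replicates 2 and 3 (0.097 and 0.0837), wild type KNO3 replicates 1, 2 and 3 (0.056, 0.0561 and 0.0549) and icpk replicate 3 (0.0525). Touch genes lost it without wild type KCl replicate 3 (0.0655) and icpk replicate 3 (0.0525), and type-A response regulators without wild type KCl replicates 1 and 3 (0.0645 and 0.0508). Clock genes lost it without wild type KCl replicates 1 and 3 (0.0634 and 0.0673) and icpk replicates 1 and 3 (0.0566 and 0.0525). The other 12 lists were not called, with adjusted p from 0.0722 for ammonium genes to 0.718, but without icpk replicate 1 the ammonium (0.0305), cytokinin (0.0331) and jasmonate lists (0.032) were called.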

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

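The fit without organelle and rRNA genes was chosen after seeing the data; the other alternatives were planned. With the replicate block icpk had 2402 higher and 2368 lower genes, type-A response regulators turned (adjusted p = 0.839), and besides the calls given with the results no other call of a named gene or list changed there. In the other comparisons same-number deviations correlated from -0.04 to 0.3 with KNO3 and from -0.22 to 0.1 against wild type KCl. There, not every library correlated best with its own number. The block gave 711 higher and 532 lower genes with KNO3, where ABI2 (0.0672), CAB3 (0.0585), OPT3 (0.0523) and CEPD2 (0.0591) were not called. It gave 594 and 750 against wild type KCl, where the CPK family (0.0605), touch (0.063) and clock lists (0.0508) were not called and cytokinin genes were (0.0165). The DESeq2 Wald test gave 788 genes lower with KNO3 and 559 shared with the higher genes in icpk. A minimum 2-fold change left 398 and 123 genes with KNO3, 370 and 732 in icpk, 277 and 352 against wild type KCl, and overlaps of 121 and 65, by its own construction. Camera with an estimated correlation called 3, 1 and 4 lists. Leaving out libraries, singly or replicate 3 of every group, gave 473 to 846 higher and 125 to 1231 lower genes with KNO3, 643 to 2348 and 765 to 2209 in icpk, and 282 to 675 and 194 to 960 against wild type KCl. Without replicate 3 of every group, 176 genes were lower with KNO3 and 108 of the lower ones were shared. Without wild type KNO3 replicate 1, icpk had 1082 higher and 1379 lower genes and the first overlap 253, and without wild type KCl replicate 2 the comparison with wild type KCl had 354 and 335. The overlap of higher with lower genes ran from 234 to 530 and that of lower with higher genes from 74 to 999. The low ends came without wild type KNO3 replicate 1 or replicate 3 of every group, where fewer libraries were tested, and both high ends of the lower genes without wild type KNO3 replicate 2, where the cause was not tested. The lists called against wild type KCl ran from 7 (without wild type KCl replicate 3) to 13. The log2 change of CPK32 with KNO3 ran from -0.19 (without wild type KCl replicate 1) to 0.30, and it was not called in any. Directions also turned in lists that were not called: adjusted p ran from 0.465 to 0.996 for type-A response regulators and from 0.263 to 0.822 for jasmonate genes in icpk. Against wild type KCl it ran from 0.189 to 0.845 for auxin genes, 0.353 to 0.987 for shoot photosynthesis markers and 0.231 to 0.934 for root markers. The causes of these turns were not tested. Of 162 results for named genes, 51 changed their side of the threshold or direction under some alternative, and of 69 list results 44 did. With 5987352 gene counts, wild type KCl replicate 3 was the shallowest library, so genes of low counts carry more counting error there than in the deeper libraries.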

Other observations

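The lists and genes in this part, and the test that leaves 1 library out of every group, were chosen after results had been seen, while what each other explanation predicts was written before its test. Genes that seedlings switch on when zinc is scarce were lower in icpk. All 9 tested genes of a zinc deficiency list, which leaves out the genes among the largest changes, were lower in icpk than in wild type with KNO3 (median log2 difference -1.07, fry adjusted p = 5.37e-05 over 5 added lists). Because the list was chosen after results had been seen, its p gives no separate support. The zinc transporter ZIP9 stood at 7.47 ± 3.07 CPM against 66.8 ± 11.3 CPM (SD, n = 3; log2 difference -3.18 ± 0.26 SE), ZIP4 at 52.6 ± 8.53 against 154 ± 27.9 CPM (-1.55 ± 0.16) and the nicotianamine synthase NAS2 at -1.43 ± 0.12. ZIP12, MTPA1, AT1G34047, AT2G36255 and AT5G33355, which are not in that list, were from 20.9-fold to 34.0-fold lower (AT2G36255 by a log2 difference of -4.10 without wild type KNO3 replicate 2). IRT3, the smallest change in the list (-0.38 ± 0.12), was not called without wild type KCl replicates 1, 2 and 3 (adjusted p = 0.0532, 0.0542 and 0.0511), wild type KNO3 replicates 1 and 3 (0.0684 and 0.125) and icpk replicates 1 and 2 (0.0937 and 0.113).

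Genes of copper use were higher in icpk, beside shoot photosynthesis markers with a median of 0.53 and root markers with -0.28. The copper superoxide dismutases CSD1 (389 ± 38.2 against 143 ± 33.8 CPM, 1.44 ± 0.17) and CSD2 (529 ± 74.9 against 125 ± 19.2 CPM, 2.08 ± 0.17) and their copper chaperone CCS (1.29 ± 0.11) were all higher. The list of these 3 transcripts was called (fry, adjusted p = 5.37e-05), but it was chosen after results had been seen, so its p gives no separate support. MIR398a, the precursor of a microRNA that targets these transcripts, had 63 pooled counts in wild type with KNO3 and 0 in icpk, which is at least 19.6-fold lower against the floor of 3 counts (11.3-fold without icpk replicate 2). Of 3 tested copper deficiency genes 2 were higher (median 0.53, adjusted p = 0.0135, and 0.0651 without icpk replicate 3). Further iron deficiency genes (7 tested, 2 higher and 1 lower, median 0.22, adjusted p = 0.0851, and 0.033 without wild type KNO3 replicate 2) and iron sufficiency genes (6 tested, 1 higher and 1 lower, median -0.03, tested as higher with 0.671, and 0.0368 without icpk replicate 1) were not called. None of the 10 genes of a seed storage list, which leaves out CRA1, had enough counts to be tested.

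The lower zinc genes were set against 2 explanations. A lost nitrate response would leave icpk at the wild type KCl level, but the median log2 difference from wild type with KCl was -0.87, with 8 of 9 genes below 0 (exact two-sided sign test, p = 0.0391), and the list's median change with KNO3 in wild type was -0.07. HMA2 (2.18 ± 0.15) and NAS2 (0.58 ± 0.12) did rise with KNO3. In icpk, NAS2 lay below wild type KCl (-0.85 ± 0.12) and HMA2 above it (0.75 ± 0.15). A reduced response therefore stays open for HMA2 and, for part of the difference, for NAS2. Calls were lost for NAS2 with KNO3 without wild type KCl replicates 1 and 2 (adjusted p = 0.0854 and 0.0629) and wild type KNO3 replicates 1 and 3 (0.0622 and 0.0623), and for HMA2 against wild type KCl without wild type KCl replicate 2 (0.0749) and icpk replicate 3 (0.0507). A smaller share of root would lower root markers alike, but their median of -0.28 lay 0.79 above that of the zinc genes (permutation test, p = 0.00462). Both the sign test and the permutation test count genes of the same libraries as independent. The zinc list was also chosen after results had been seen. Neither p can therefore reject its explanation, and the values show only where the zinc genes lay beside wild type KCl and the root markers. A lasting difference of the icpk line, in its zinc status or its background, may account for the pattern as a hypothesis; it was not tested, since no icpk libraries with KCl were analysed here.

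More genes were called between icpk and wild type than between KNO3 and KCl, by a ratio of 3.81. It was 5.98, 6.88 and 4.68 without wild type KCl replicates 1, 2 and 3, 2.12 without wild type KNO3 replicate 2, 2.27 without icpk replicate 3 and 2.08 without replicate 3 of every group. A left-out wild type KCl library shrinks only the nitrate comparison and a left-out icpk library only the icpk comparison. Ratios from such fits are therefore unbalanced. Thinning all libraries to 5987352 counts left 3493 and 1032 calls, a ratio of 3.38 (3.11 with the replicate block). This argues against uneven depth, with wild type KCl replicate 3 the shallowest library, as the whole cause. With 1 library left out of every group, the median ratio of 9 fits was 2.09 without the outlying wild type KCl replicate 3 (1.63 to 3.87), and 2.98 and 3.13 without replicates 1 and 2. The lowest ratio, 1.63, came from a fit without both wild type KCl replicate 3 and icpk replicate 3. Fits without icpk replicate 3 that kept wild type KCl replicate 3 gave 1.77 to 2.84. Fits without wild type KCl replicate 3 that kept icpk replicate 3 gave 1.99 to 3.87, so wild type KCl replicate 3 is not singled out. These single libraries and a difference between the lines that does not depend on nitrate cannot be told apart as causes. Each may contribute.

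The 336 genes that were lower with KNO3 and higher in icpk are less secure. The shared wild type KNO3 libraries alone gave at most 1 such gene in simulations of unchanged libraries. Hardly any gene is called when no group differs, so this count cannot show what the sharing adds among real calls. With the mean photosynthesis marker level as a covariate, 4 of the 336 genes (1.2%) passed in both comparisons, but all calls fell to 340 with KNO3 and 100 in icpk, so few could pass whatever the cause. All 336 kept their directions, with median log2 changes going from -0.73 to -0.49 with KNO3 (median SE 0.157 and 0.200) and from 0.88 to 0.62 in icpk (0.156 and 0.216). The groups explain 66.7% of that covariate's variance, so a different shoot share of the wild type KNO3 libraries and a change with nitrate and genotype cannot be told apart.

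Other splits of the 6 libraries of each comparison into 3 and 3 make 10 splits, too few for a share under 0.05. The real split called 1207 genes with KNO3, 4599 in icpk and 1418 against wild type KCl, and the highest of the other splits called 1, 0 and 0, so 1 split, the real one, was as large in each. In icpk, 3 of the other splits part all 3 same-number pairs as the real one does and 6 part 1 pair, and each called 0 genes.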
